A study of Arabidopsis thaliana with 9 samples.

How the data were processed

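The deposited table holds 9 Affymetrix ATH1 arrays of Arabidopsis thaliana leaf RNA, 3 from each of 3 genotypes in the Col-0 background, with 1 value for each of 22810 probe sets. Per the labels' protocols, total RNA was extracted with a Qiagen kit and labelled with biotin by the one-cycle method. Per the submitters' processing notes, the deposited intensity values were made with MAS5 in GCOS, which condense the probes of a probe set to 1 signal on a linear scale. The values bear out a common scaling by the authors: the mean signal after trimming 2% at each end was 100.01 on all 9 arrays. Detection calls were not used here. Scaling every array to the same mean removes any difference in total transcript level between groups, so each change is relative to the rest of the array.

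Groups and replicate numbers were taken from the submitted labels. The labels number the replicates but do not say whether they came from separate plants or pots, so p-values measure the spread between these samples, which may be partly technical. Median signals ran from 33.1 to 35.7 across arrays. No 2 arrays held identical values, and correlations of log2 signals within a group lay between 0.9593 and 0.9857. The number of arrays limits the precision of each value.

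Probe sets were named through the platform annotation, which lists 1 gene for 13513 probe sets, several for 503 and none for 8794; 13436 of the single-gene probe sets were matched to a gene of the TAIR10.1 RefSeq table, and the others kept the annotation's name. Of the 14151 probe sets tested, 7710 had 1 gene, 277 had several and 6164 had none listed. No probe set was paired with DEK1, so its own transcript is not analysed here. No gene was named from a probe set with several genes.

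Signals were transformed as log2(signal + 3.63), the pseudocount being the 20th percentile of the table, so fold changes of genes with low signals are understated. A probe set was tested if its signal reached 17.6, the 40th percentile, on at least 3 arrays; 64 control probe sets were left out. Linear models were fitted with limma 3.58.1 in R 4.3.3 to all 9 arrays at once, with 3 group means, 6 residual degrees of freedom and empirical Bayes moderation with an intensity trend. Tests were two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, with no fold limit. The 3 groups were also compared with a moderated F-test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

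Before the data were examined, 32 gene lists with 593 entries, the tests, the alternatives and the rule for naming genes were fixed. The rule took, for each comparison, up to 12 rises and 12 falls with the largest log2 fold change among called single-gene probe sets whose groups did not overlap and whose higher group mean was at or above the table's median signal of 34.4, plus up to 4 members with the smallest p from each gene list. Of the list entries, 83 had a usable probe set, and 5 more were left out because the locus carried another name. Lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. As the annotation left only 2 lists of that size, 33 families were added by symbol, drafted from the annotation but written down only after a first fit and its highest-ranked genes had been seen, GH9B8 among them; glycosyl hydrolase family 9 was not in that draft. Of the families, 26 had at least 5 tested members.

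The fit was tested on simulated data with the real means and spread. For calpain overexpressing minus wild type, it recovered 82 of 100 probe sets changed 2-fold and 100 of 100 changed 4-fold among 14151 probe sets, with 8 false calls. The corresponding figures were 80 and 100 with 7 false calls for calpain null minus wild type, and 80 and 96 with 12 false calls for calpain overexpressing minus calpain null. The simulated noise was normal and independent, with no outlying array, so these figures may not hold for the real arrays. Alternatives covered the pseudocount, the filter, quantile normalization, median centring, the intensity trend, array weights, fits of only 2 groups, the replicate number as a block, cross-hybridising probe set types and each array left out in turn.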

Results

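The series profiled leaves of Arabidopsis plants at growth stage 1.14 on 9 arrays. The wild type was Col-0. The other 2 lines were labelled as carrying a T-DNA knock-out of At1g55350, the locus of DEK1, together with a transgene labelled as the ADEK1 calpain, overexpressing, in one line and as calpain null in the other; the labels do not say what null stands for. The annotation, which lists no gene for 8794 probe sets, paired none with DEK1 itself, so its transcript is not analysed here. Whether an unlisted probe set reads DEK1 or the transgene was not determined. Calpains are calcium-dependent cysteine proteases, and DEK1 is the plant member of that family, a membrane protein needed for epidermis formation. Each group had 3 arrays. Seeds were kept in the cold for 3 days, seedlings moved from plates to soil after 7 days, and plants were grown at 21 °C in short days, 6 to a pot. All values are MAS5 signals given as mean ± SD with n = 3, and p-values are limma's, adjusted by Benjamini-Hochberg.

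The first principal component held 40% of the variance and the second 18.3%. Wild-type arrays scored from -33.2 to -19.2 on the first. The calpain null arrays scored -9.62, 15.8 and 14.7, and the calpain overexpressing arrays -9.37, 27.1 and 34.5, the array numbered 1 being the nearest to wild type in both lines. The second component separated the lines, with calpain overexpressing arrays between 10.8 and 19.0 and calpain null arrays between -26.5 and -13.4. The 25S rRNA control signal was 167 on the calpain null array numbered 1 and 160 on the calpain overexpressing array numbered 1, and 208 to 384 on the other 7.

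**Figure D1:**
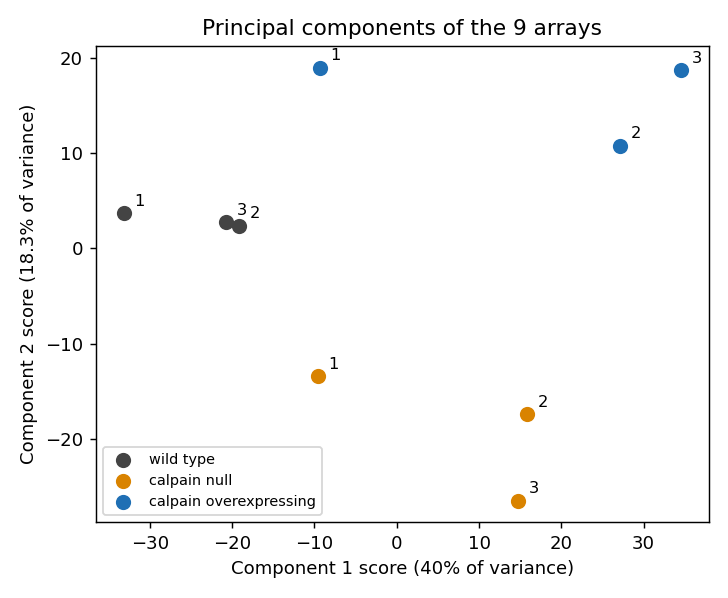
Scores of the 9 arrays on the first 2 principal components of log2 signals (horizontal axis 40% of the variance, vertical axis 18.3%); each point is an array, coloured by group and marked with its replicate number. Both arrays numbered 1 of the non-wild-type lines, at -9.62 and -9.37 on the horizontal axis, lie nearest to the wild type of their group.

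The comparison of calpain overexpressing with wild-type leaves asks which transcripts differ in the line labelled as overexpressing the calpain. XTH19 (AT4G30290), a xyloglucan endotransglucosylase/hydrolase that cuts and rejoins wall xyloglucan, went from a signal of 2.37 ± 2.55 to 212 ± 209, a log2 fold change of 4.64 (SE 0.68, adjusted p = 0.00859). AT1G62770, a pectin methylesterase inhibitor type protein, rose from 9.91 ± 4.48 to 260 ± 204 (log2 fold change 3.93, adjusted p = 0.00733). AT4G32460, which encodes a DUF642 wall protein, rose from 276 ± 49.6 to 1996 ± 869 (2.74, adjusted p = 0.00273), and ARL (ARGOS-like), a regulator of organ size through cell expansion, from 31.4 ± 8.38 to 347 ± 174 (3.18, adjusted p = 0.0466); ARL had 181 ± 135 in calpain null leaves. In all, 228 of 14151 probe sets were called, 114 higher and 114 lower, of which 114 had a single named gene; 2566 had an unadjusted p under 0.05.

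Other large rises were AT4G35720, from 0.963 to 162 (log2 fold change 4.95, adjusted p = 0.000606), AT5G24240, a gamma-type phosphatidylinositol 4-kinase, from 1.32 to 61.4 (3.71, adjusted p = 0.00162), and AT2G43870, a pectin lyase-like protein, from 5.91 to 95.7 (3.3, adjusted p = 0.0146). AT5G22460 (log2 fold change 2.67), the ERF-type factor AT1G44830 (2.64), the SAUR-like AT3G53250 (2.64), the acyltransferase-like AT5G01210 (2.60) and AT5G17780 (2.27) had adjusted p values from 0.0172 to 0.0478. The wild-type means of AT4G35720, XTH19, AT1G62770, AT5G24240, AT2G43870, AT3G53250 and AT5G17780 lay below the filter signal, where fold changes depend on the pseudocount. The calpain overexpressing arrays numbered 1, 2 and 3 had XTH19 signals of 36.2, 157 and 443 and AT4G32460 signals of 1053, 2168 and 2765. ARL had 27.2 on the calpain null array numbered 1 and 280 and 235 on the arrays numbered 2 and 3.

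ZW9 (AT1G58270) dropped from 731 ± 40 to 300 ± 8.25, a log2 fold change of -1.28 (SE 0.11, adjusted p = 0.000369), and AT3G26935, of the DHHC protein acyltransferase family, from 76.5 ± 1.38 to 23.9 ± 5.13 (-1.56, adjusted p = 0.0013); neither was called in calpain null leaves, which had 753 ± 103 and 79.9 ± 11.7. AT3G28270 fell by 2.74 on the log2 scale (adjusted p = 0.0293), AT5G05600 by 2.45 (adjusted p = 0.0217) and the MATE-type transporter AT1G66760 by 1.78 (adjusted p = 0.00703). The calpain overexpressing means of AT3G28270 and AT5G05600, 5.04 and 13.2, lay below the filter signal, where fold changes depend on the pseudocount. The thionin gene AT1G66100 went from 1231 ± 466 to 465 ± 87.0 (adjusted p = 0.0422) and the GDSL-type lipase AT4G28780 from 302 ± 12.4 to 131 ± 62.2 (adjusted p = 0.0275). AT5G07810, AT5G38300, AT5G62550, AT3G15630 and AT5G05180 had log2 fold changes from -1.47 to -1.26. On the calpain overexpressing arrays numbered 1, 2 and 3, ZW9 had 308, 299 and 292. Of the 24 named genes with the largest changes, 6 kept their call under every alternative run: AT4G35720, AT5G24240, AT4G32460, ZW9, AT3G26935 and AT1G66760. The others missed the threshold under at least 1, with an adjusted p of up to 0.195 for ARL.

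Of 8 expansins tested, which loosen walls in growing cells, 2 rose and none fell: EXPA4 went from 193 to 329 (log2 fold change 0.76, adjusted p = 0.0162) and EXPB3 from 258 to 503 (0.97, adjusted p = 0.0431), with 3 rises when adjusted over the list alone. The list was higher by camera (adjusted p = 0.014), but not with an estimated correlation (adjusted p = 0.19) or on ranks (adjusted p = 0.057). Of 4 xyloglucan endotransglucosylases tested, XTH19 and XTH32 rose, the latter from 440 to 637 (0.53, adjusted p = 0.0361); XTH16 (-0.57) and XTH27 (-0.37) fell when adjusted over the list alone. EXPA4, EXPB3 and XTH32 missed the threshold under at least 1 alternative, with adjusted p of up to 0.095, 0.165 and 0.174. Among 6 endoglucanases of glycosyl hydrolase family 9, a family added after GH9B8 had been seen among the highest-ranked genes, 3 rose: GH9B8 from 84.1 to 349 (2.00, adjusted p = 0.00273), GH9C2 from 416 to 971 (1.2, adjusted p = 0.0172) and GH9B13 from 81.2 to 165 (0.97, adjusted p = 0.0243). GH9C2 and GH9B13 missed the threshold under at least 1 alternative, with adjusted p of up to 0.095 and 0.109. The family's camera adjusted p was 0.00058, and its adjusted p = 0.67 with an estimated correlation.

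**Figure D2:**
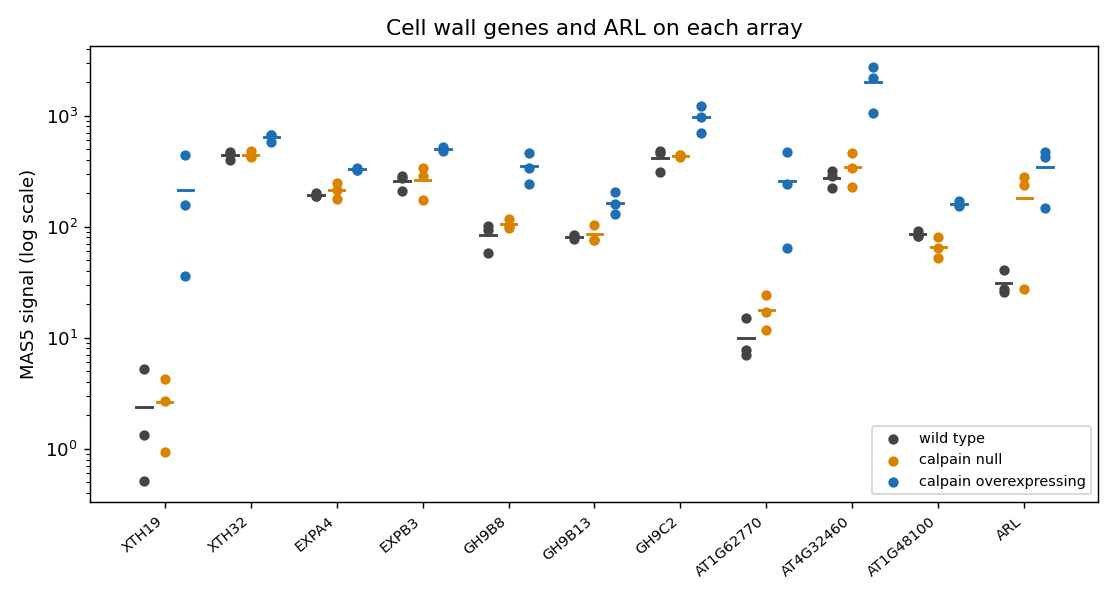
MAS5 signal (log axis) of selected cell wall genes and ARL on each array, by group. Points are arrays and short lines are group means of 3 arrays. All wall genes shown were higher in calpain overexpressing than in wild-type leaves. Tested wall genes that were not, such as XTH16 and XTH27, are left out. XTH19 means were 2.37 in wild type, 2.62 in calpain null and 212 in calpain overexpressing leaves, and those of GH9C2 were 416, 438 and 971.

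None of the 10 photosynthesis genes tested was called over all probe sets; RCA, the Rubisco activase gene, had 5277 in wild-type and 4926 in calpain overexpressing leaves (log2 fold change -0.10, adjusted p = 0.649), and LHCB4.3 had 69.6 and 128 (0.88, adjusted p = 0.0753). Among cell cycle genes, PRL had -0.50, AUR1 -0.41 and AUR2 -0.67 (adjusted p from 0.26 to 0.33), none called. Epidermal identity was covered by 1 gene, ACR4, with signals of 38.2 and 30.5 (adjusted p = 0.525), and the stomatal genes SPCH, MUTE, FAMA and STOMAGEN lay between -0.43 and 0.01, none called. COR15A, COR47, XERO2 and COR15B of the cold and drought list lay between -0.74 and -0.12, none called over all probe sets. The cytokinin response gene ARR16 had 0.72 (adjusted p = 0.0611) and was called in 7 of 20 alternatives. Adjusted over the list alone, LHCB4.3, IAA29, ARR16 and GI were higher and COR47 and UGT74B1 lower; GI was the only tested gene of its list, so its p was not adjusted there. The lists for cuticle, endoreduplication, cellulose synthesis, secondary wall, touch, salicylic acid, jasmonate, senescence, evening clock, leaf polarity, trichome, heat shock, glucosinolate, root and phloem had 1 or 2 tested genes each, none called in any comparison over all probe sets. The root marker PYK10 had signals of 25.9, 34.3 and 47.7 in wild-type, calpain null and calpain overexpressing leaves, and the reference transcript UBC21 had 212, 203 and 221.

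Among probe sets unnamed here, the 2 rises with the smallest p were 259646_at, from 113 ± 8.12 to 1747 ± 141 (log2 fold change 3.91, adjusted p = 1.98e-09), and 252607_at, from 10 to 192 (3.74, adjusted p = 0.000369). The falls were 245576_at, from 262 ± 50.1 to 10.5 ± 7.42 (-4.39, adjusted p = 0.000262), and 259878_at, from 114 to 17.7 (-2.48, adjusted p = 0.00127). The count of 228 depended on single arrays: it became 1789 without the calpain overexpressing array numbered 1 and 367 without the calpain null array numbered 1, and 26 and 49 without the calpain overexpressing arrays numbered 2 and 3. It was 58, 55 and 30 without the wild-type arrays numbered 1, 2 and 3, 2663 with array weights, and 1923 without the arrays numbered 1 of all groups, an alternative chosen after seeing the data.

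The comparison of calpain null with wild-type leaves asks which transcripts differ in the line labelled calpain null. In all, 8 probe sets were called, 7 higher and 1 lower, while 2469 had an unadjusted p under 0.05. The leucine-rich repeat receptor kinase gene AT1G35710 rose from 25.1 ± 4.13 to 81.6 ± 5.84 (log2 fold change 1.58, adjusted p = 0.00865), and AT4G08850, a receptor kinase gene also known as MIK2, from 121 ± 5.96 to 277 ± 32.1 (1.17, adjusted p = 0.0205). AT5G55450, which encodes a lipid-transfer-like protein, rose from 622 ± 148 to 1552 ± 142 (1.34, adjusted p = 0.0131), and AT1G01240 from 85.6 ± 9.70 to 197 ± 27.6 (1.16, adjusted p = 0.0344). Both receptor kinase genes lay near wild type in calpain overexpressing leaves, at 27.9 and 112. The unnamed 259646_at rose to 2175 ± 158 (4.23, adjusted p = 8.04e-10) and 259878_at fell to 21.5 ± 6.45 (-2.24, adjusted p = 0.00865).

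No list was called in this comparison, and 1 list, photosynthesis, was called by camera on ranks (adjusted p = 0.037, against adjusted p = 0.059 by camera and adjusted p = 0.44 with an estimated correlation). Of the auxin response genes, IAA29 had 7.34 in wild-type and 103 in calpain null leaves (log2 fold change 2.87, adjusted p = 0.0995), GH3.5 30.1 and 94.2 (1.38, adjusted p = 0.116) and HAT2 44.0 and 88.6 (0.88, adjusted p = 0.169), while GH3.3 was not called (adjusted p = 0.991), 3 of 4 being higher when adjusted over the list alone and none over all probe sets. IAA29, GH3.5 and HAT2 were called over all probe sets in 6, 5 and 4 of 20 alternatives, with adjusted p down to 0.000145, 0.00887 and 0.00514, each without the arrays numbered 1 of all groups. The flavonoid glycosyltransferase gene UF3GT had 30.1 and 6.24 (-1.77, adjusted p = 0.111). Of 3 endoplasmic reticulum stress factors, BZIP60 had 0.55 (adjusted p = 0.14), BZIP28 0.38 and BZIP17 0.32, none called over all probe sets and 2 when adjusted over the list alone. Adjusted in that way, CML38, SAG101 and GI were also higher and SPCH, UF3GT and UGT74B1 lower, with no adjustment for SAG101 and GI, each the only tested gene of its list. Each of the 4 named rises missed the threshold under at least 1 alternative, with an adjusted p of up to 0.205 for AT1G01240. The count of 8 became 491 without the calpain overexpressing array numbered 1, 232 without the calpain null array numbered 1, 27 without the calpain overexpressing array numbered 2, 3 without the calpain null array numbered 3 and 1 without the wild-type array numbered 3. It was 263 in a fit of these 2 groups alone, 619 with array weights and 1122 without the arrays numbered 1 of all groups.

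The direct comparison of the 2 transgenic lines asks which transcripts differ between the lines labelled calpain overexpressing and calpain null. XTH19 rose from 2.62 ± 1.66 in calpain null to 212 ± 209 in calpain overexpressing leaves (log2 fold change 4.54, adjusted p = 0.0156), AT4G32460 from 342 ± 117 to 1996 ± 869 (2.48, adjusted p = 0.00594) and AT1G62770 from 17.8 ± 6.39 to 260 ± 204 (3.27, adjusted p = 0.0258). The endoglucanase genes GH9B8 (1.65, adjusted p = 0.0114), GH9C2 (1.1, adjusted p = 0.0357) and GH9B13 (0.91, adjusted p = 0.045) rose here too, and AT1G48100, of the polygalacturonase family, from 66.1 ± 14.7 to 160 ± 7.89 (1.25, adjusted p = 0.00399). In all, 74 probe sets were called, 35 higher and 39 lower, with 1507 at an unadjusted p under 0.05.

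Further rises were AT4G35720 (log2 fold change 4.38, adjusted p = 0.00186), AT5G24240 (3.36, adjusted p = 0.00399), AT3G51410 (2.87, adjusted p = 0.0388), AT1G07440 (1.39, adjusted p = 0.0282), the translation elongation factor gene AT5G12110 (1.35, adjusted p = 0.00532) and AT5G06270 (1.11, adjusted p = 0.00186). Falls included ZW9 (-1.31, adjusted p = 0.000557), AT3G26935 (-1.61, adjusted p = 0.00185), AT2G30930 (-1.68, adjusted p = 0.0278) and the receptor kinase genes AT1G35710 (-1.44, adjusted p = 0.00399) and AT4G08850 (-1.29, adjusted p = 0.00413). AT5G44820, AT1G62510, AT5G65380, AT2G30600, AT1G78170, AT4G22560 and AT3G05730 fell by 0.54 to 1.25 on the log2 scale. Under every alternative run, 10 of these 24 genes kept their call: AT4G35720, AT5G24240, AT4G32460, AT5G12110, AT1G48100, AT5G06270, AT3G26935, AT1G35710, ZW9 and AT4G08850. The expansins were not called as a list (adjusted p = 0.076), although 2 were higher when adjusted over the list alone. XTH32, WSD1, LHCB4.3, ARR16 and UF3GT were also higher, and SAG101, WRKY6 and XTH27 lower, in that way, with no adjustment for WSD1, SAG101 and WRKY6, each the only tested gene of its list. EXPA4 had 0.63 (adjusted p = 0.052) and EXPB3 0.96 (adjusted p = 0.0685), called in 6 and 4 of 20 alternatives. The glycosyl hydrolase family 9 had a camera adjusted p of 8e-05 and an adjusted p = 0.3 with an estimated correlation. This family was added after GH9B8 had been seen among the highest-ranked genes, so neither p is an independent test. GH9B8, GH9C2 and GH9B13 missed the threshold under at least 1 alternative, with adjusted p of up to 0.06, 0.149 and 0.176. The count of 74 became 172 without the calpain overexpressing array numbered 1, 43 and 26 without those numbered 2 and 3, 34 and 25 without the calpain null arrays numbered 2 and 3, and 46 and 35 without the wild-type arrays numbered 2 and 3. It was 24 in a fit of these 2 groups alone, 238 with array weights and 373 without the arrays numbered 1 of all groups.

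Among all 3 groups, 164 probe sets differed by the F-test. Of the genes named for calpain overexpressing minus wild type, ARL, AT5G22460, AT3G53250, AT5G01210, AT5G17780, AT3G28270, AT5G38300 and AT5G62550 missed that test's threshold. Their F-test adjusted p values ran from 0.052 to 0.0815. Of the probe sets called, 44 changed the same way in calpain overexpressing leaves against both other groups, 27 higher and 17 lower. Independent lists would share 0.28 and 0.31, and simulated unchanged groups shared at most 1. Neither figure shows how much of the 44 comes from the calpain overexpressing arrays that both comparisons share. The simulation held no change to call. XTH19, AT4G32460, GH9B8 and ZW9 are among the 44. Against wild type, 3 probe sets changed the same way in both lines: AT5G55450 and 259646_at rose, and 259878_at fell. Independent lists would share 0.056 higher and 0.0081 lower, figures that leave out the sharing of the wild-type arrays. The fold changes of both lines against wild type correlated across probe sets at r = 0.64, where the shared wild-type arrays alone gave 0.5 in simulation, and their covariance was 0.0831 against a simulated 0.0196. Probe sets are not independent replicates. Of the 228 called in calpain overexpressing leaves, 207 (90.8%) had the same sign in calpain null leaves, at a median of 42.1% of the change. With calpain null unchanged, simulated medians were 56.4% for the sign and 2.71% for the change, and at most 63.5% and 5.79%. That simulation took the selected changes as true and drew independent noise, so it may understate what sharing wild-type arrays gives. With 1 wild-type array kept out of the calls and used alone for calpain null, the same sign held for 75.9%, 81.8% and 86.7%. The median change was then 14.3%, 14.6% and 22.5%. With 3 wild-type arrays the controls could not be split into 2 sets with replicates, so part of the excess over the simulation may come from sharing them. Without the calpain overexpressing array numbered 1, the counts of 164, 44 and 3 became 1447, 142 and 315, and without the calpain null array numbered 1 the first and last became 406 and 69. The count of 164 became 80, 48 and 35 without the wild-type arrays numbered 1, 2 and 3, 71 without the calpain null array numbered 3, and 61 and 55 without the calpain overexpressing arrays numbered 2 and 3. The count of 44 became 27, 20 and 13 without the wild-type arrays numbered 1, 2 and 3, 21 and 17 without the calpain null arrays numbered 2 and 3, and 16 and 13 without the calpain overexpressing arrays numbered 2 and 3. The count of 3 became 1 without the wild-type array numbered 3.

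**Figure D3:**
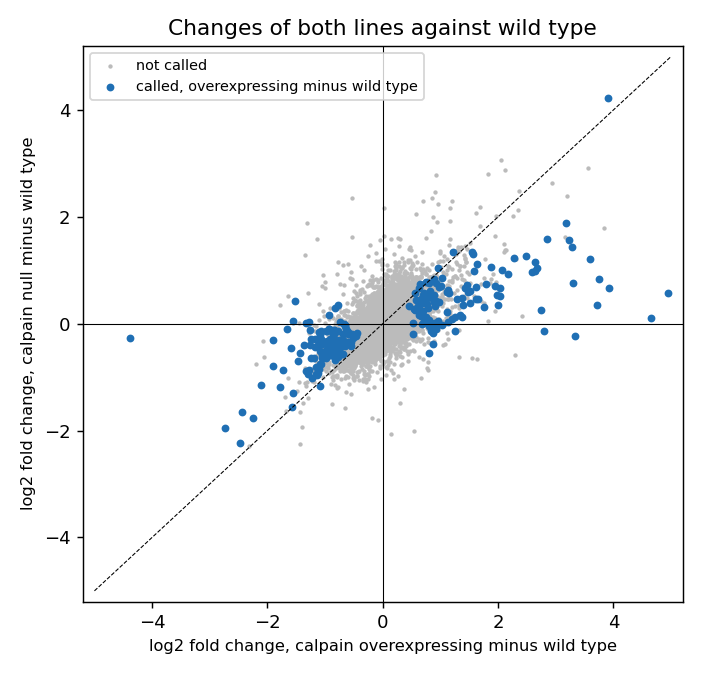
Log2 fold change against wild type in calpain overexpressing (horizontal axis) and calpain null leaves (vertical axis) for the 14151 probe sets tested; blue points are the 228 called in calpain overexpressing minus wild type, and the dashed line marks equal change. Of the blue points, 207 have the same sign on both axes.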

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

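The alternative that leaves out the arrays numbered 1 of all 3 groups was chosen after seeing the data; the others were planned. No called gene, probe set or list that was run under the alternatives changed direction; LCR69, AT1G68570 and the added families other than glycosyl hydrolase family 9 were not run. With the replicate number as a block, the counts for calpain overexpressing minus wild type, calpain null minus wild type and calpain overexpressing minus calpain null were 770, 461 and 187, 869 probe sets differed among the 3 groups, 111 changed in calpain overexpressing against both other groups and 181 in both lines against wild type; the numbers were not taken as pairs, since the labels give none and 3 of the 9 same-numbered pairs deviated together at r above 0.1 (from -0.13 to 0.37), and 1 array deviated most like its own number in both other groups. In the same order, array weights gave 2663, 619, 238, 2249, 169 and 393, and leaving out the arrays numbered 1 gave 1923, 1122, 373, 1910, 222 and 676. Without the filter, calpain overexpressing minus wild type had 76 calls, calpain overexpressing minus calpain null 39, the F-test 65 and the overlap against both other groups 22, with more probe sets tested. With the filter at the 60th percentile, calpain null minus wild type had 16 calls and the F-test 106. Without the intensity trend, the first comparison had 102 calls, the F-test 77 and the overlap against both other groups 28. Fits of only the groups compared gave 263 calls for calpain null minus wild type, 24 for calpain overexpressing minus calpain null, 15 for the overlap against both other groups and 28 for both lines against wild type, with 4 residual degrees of freedom. Leaving out 1 array at a time, in the order of the 6 counts, gave ranges of 26 to 1789, 1 to 491, 25 to 172, 35 to 1447, 13 to 142 and 1 to 315; the highest value of each came without the calpain overexpressing array numbered 1, and an arm of 2 arrays is then assumed to vary like the others. The 1 list called in calpain overexpressing minus wild type became 0 with an estimated correlation, on ranks, without the filter and without the arrays numbered 1, and 0 to 2 when 1 array was left out. Calpain null minus wild type went from 0 to 1 list on ranks and 0 to 2 with 1 array left out, and calpain overexpressing minus calpain null from 0 to 1 list with the filter at the 60th percentile, with array weights and without the arrays numbered 1, and 0 to 1 with 1 array left out. Leaving out an array of the group not compared leaves the 2 compared means unchanged. The rise from 8 to 491 calls in calpain null minus wild type therefore came through the spread estimated over all groups. Beyond this and what fewer arrays or fewer probe sets account for, the cause of the shifts was not tested. Both pseudocounts, quantile normalization, median centring and leaving out cross-hybridising probe set types kept all 6 counts within 1.5 times. Of 70 calls of named genes and probe sets, 41 were lost without the wild-type array numbered 3, and 36 and 34 without the calpain overexpressing arrays numbered 2 and 3. Of 175 such values not called, 30 gained a call under at least 1 alternative, 26 without the arrays numbered 1 and 24 with array weights. Low signals limit the data, as for XTH19 in wild type. The DEK1 transcript could not be run under any alternative.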

Other observations

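Tests of other groupings of the arrays were set out before their results were seen. The tests of the families added by symbol, of the joined wall set, of the arrays numbered 1 and of the position of the calpain null line were chosen after the result was seen, and the draws of splits for the shared probe sets, the mixture test, the RNA degradation test and the bound for the calpain null position were changed after a first outcome. For RNA degradation, ratios inside the range of the other arrays first counted against it on the calpain overexpressing array, and now leave it open. Every draw is given, and the mixture test is the last of 4 versions: 2 on positions, on the log2 and the signal scale, decided nothing, and the third missed its bound. Among the families added by symbol, the 15 ribosomal protein genes tested were lower in 14 cases in calpain overexpressing minus wild type (median log2 fold change -0.20, camera adjusted p = 0.017, adjusted p = 0.68 with an estimated correlation), and no member was called. All 8 autophagy genes had higher values there (median 0.34, camera adjusted p = 0.029, adjusted p = 0.68 with an estimated correlation), with none called; ATG8F had 356 in wild-type, 511 in calpain null and 516 in calpain overexpressing leaves. The 9 CYP71B cytochromes P450 had a median of 0.30 (camera adjusted p = 0.029, adjusted p = 0.67 with an estimated correlation), with none called. In calpain overexpressing minus calpain null, 1 of 6 NPF transporter genes rose, AT1G68570 from 91.6 to 137 (0.56, adjusted p = 0.0455), with a family median of 0.39 (camera adjusted p = 0.04, adjusted p = 0.3 with an estimated correlation). All 9 exocyst and SEC genes had lower values there, with none called (median -0.16, camera adjusted p = 0.044, adjusted p = 0.81 with an estimated correlation). LCR69, a defensin-like peptide gene, rose from 1107 to 2252 in calpain overexpressing leaves (1.01, adjusted p = 0.0448), and the unnamed 259646_at lay between 106 and 122 on wild-type arrays and between 1654 and 2272 on the other 6.

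The wall genes were examined as a set of 18, joining the expansins, the xyloglucan endotransglucosylases and glycosyl hydrolase family 9. Its median log2 fold change was 0.45 in calpain overexpressing minus wild type, 0.28 against calpain null and 0.08 in calpain null minus wild type. The scaling of the arrays stays open for absolute levels, since it fixes the median change of all tested probe sets near 0 (0.0059). A hypothesis is that these transcripts rise together in the line labelled calpain overexpressing. Camera with an estimated correlation of 0.12 gave p = 0.035 against wild type and p = 0.029 against calpain null. Of the members, 7 and 4 rose, and 13 and 12 of the 18 had higher values. In calpain null minus wild type, 13 had higher values as well. The set was joined after the families' values were known, and both comparisons use the same calpain overexpressing arrays. The p values may therefore overstate the evidence and are no independent test of the hypothesis. Neither the expansins nor family 9 alone passed with an estimated correlation in either comparison. The joined set was not run under the alternatives. A difference in leaf age or tissue makeup between lines was not tested.

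The arrays numbered 1 of both transgenic lines lay nearer to wild type on the first principal component. Wild-type RNA mixed into or swapped for the calpain overexpressing array is argued against as the whole cause: its median position, 42.0% of the way from wild type over 136 probe sets specific to that line (18.0% over 911 shared by both lines, where the calpain null array lay at 40.2%), needs 58% wild-type RNA, and the shared ones more, but 6 of 106 falling probe sets lay over 3 SD below what that share alone would give (exact binomial p = 2.6e-06, which takes probe sets as independent), ZW9 and 245576_at among them. Over all 461 falling probe sets the same 6 gave an exact binomial p = 0.0068, above the bound of 0.001 set for the test, but the further ones lay too high on the other 2 arrays to go below without mixing either; a smaller share stays open. Wild-type RNA mixed into or swapped for the calpain null array was not tested and stays open. RNA degradation stays open for both arrays. By the rule, only 3 ratios of 3′ to 5′ control signals all below the other 7 arrays would count against it. On the calpain overexpressing array, 0 of 3 ratios lay outside the range of the other 7. These ratios thus give no sign of degradation there. On the calpain null array, 2 of 3 lay outside that range. The 25S rRNA signal, which was not part of this test, was lowest on both arrays, at 160 and 167 against 208 to 384. A batch acting alike on the arrays numbered 1 of all groups is argued against by a correlation of -0.01 between the deviations of wild type and calpain null, but the calpain overexpressing array correlated at 0.32 and 0.37 with these, above the 0.27 reached by arrays of unlike number, so a batch shared by fewer arrays stays open.

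Most probe sets called in calpain overexpressing minus wild type had the same sign in calpain null, at a median of 42.1% of the change. Wild-type arrays shared by both comparisons are a candidate explanation: in 100 simulations with calpain null unchanged, at most 63.5% of called probe sets had the same sign in both, against the observed 90.8%, but a simulation alone excludes nothing. With 1 wild-type array kept out of the calls and used alone for calpain null, the share was 75.9%, 81.8% and 86.7% of 58, 55 and 30 called probe sets, and the median ratio 14.3%, 14.6% and 22.5%. All 3 shares met the bound of 75% set before that run, which would argue against shared arrays as the whole cause, but a condition added after they were seen, that the lowest clear it by more than their SD, was not met, so this stays open. A shared effect of the transgene or of the knock-out background stays open, untested.

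The 10 splits of 6 arrays are too few for a share under 0.05. The real split gave 228, 8 and 74 calls in the 3 comparisons, in the order of the report, and the highest other split 0, 1 and 1. For lists called, the real splits gave 1, 0 and 0 and the highest others 2, 2 and 1; 4, 10 and 10 of the 10 splits gave as many lists. Among 100 splits of 9 arrays, only the real 1 reached the 164 calls of the F-test, the highest other giving 54. A random grouping of these arrays is thus an unlikely source of that count. The splits cannot tell a difference between lines from a pot or batch difference that follows the lines. The same held for the 44 changed in calpain overexpressing against both other groups, where the highest other split gave 2 and further draws of 100 gave 2 and 13. For the 3 changed in both lines against wild type, 7 of 100 splits gave as many, the highest 17. Other groupings thus separated the arrays as well, for a reason not tested, and chance cannot be excluded for this count. Regrouped arrays still carry differences between lines, so these splits cannot show chance as the source either. The count was 315 without the calpain overexpressing array numbered 1. Further draws of 100 splits, made after the 7 were seen, had 2 and 1 as large. The splits counted probe sets and did not test these 3 singly. In each of the 3, the signals of neither line overlapped those of wild type. Of all 14151 tested probe sets, 21.9% did not overlap in calpain overexpressing minus wild type and 24.6% in calpain null minus wild type. The 3 had been called in both comparisons, so their lack of overlap adds no separate support. The unnamed one of the 3 that rose, 259646_at, had 106 to 122 on wild-type arrays and 1654 to 2272 on the others. Whether it reads DEK1 or the transgene was not determined, so it cannot be taken as a downstream response.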
